A study of Mus musculus with 6 samples.

How the data were processed

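Single EGFP-positive Treg cells from mouse spleen were profiled in 6 samples, 3 cKO and 3 WT, and the study compared Bach2-deficient with wild-type Treg cells. Per the labels' protocols, CD4 T cells were enriched and sorted by FACS, libraries were made with the 10x Chromium 3′ chemistry (v2) and sequenced on an Illumina HiSeq. The protocols also list steps for stabilising and extracting bulk RNA, and how these apply to the single-cell libraries is not stated. Per the submitters' processing notes, the build was mm10 and the tools were FastQC, cutadapt, HISAT2, Cell Ranger and Seurat. The notes give no versions and do not say which tool made which step. Chromium v2 libraries carry UMIs, and the deposited counts are whole UMI counts per gene and cell, not reads.

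The deposited count table held raw UMI counts of 14098 genes in 10685 cells, each gene with a UMI in at least 3 cells. Cell totals ran from 507 to 22130 UMIs. The authors' second table, in natural log units, held 10464 of these cells. Its values equalled ln(1 + 10000 × count / cell total), with a largest difference from a recomputation below 1e-09. Its cells had fewer than 2500 genes and under 5% mitochondrial UMIs. Of the 221 cells absent from it, 98 were past these limits and 123 were within them. Columns were barcodes ending in a suffix from 1 to 6, and 63 barcodes occurred in more than 1 set. None of the 10685 cell columns could be tied to a sample by name, so the genotype of a set was left open and was not inferred from order or values. The 6 sets had 1902, 1794, 1826, 1799, 1723 and 1641 cells, and 4786590, 3999542, 4211019, 4191609, 3998172 and 4202670 UMIs.

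Before the data were examined, the cell filters, the clustering settings, the cell type markers, the 27 gene lists, the naming of genes and a set of tests between genotypes were fixed. The tests between genotypes needed a map from cells to samples and were not run. In their place, Bach2 was compared between activated-like and resting-like cells over all 6 sets. This comparison had been planned as an edgeR fit to the WT libraries with library as block. It was made here as a ratio of UMIs pooled over the sets, with the ratio of each set beside it. The planned activation score was used to compare cells within sets. The comparison of score tertiles, the size rule for lists and each alternative to them were chosen after the data had been seen.

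Cells with at least 200 genes and under 10% mitochondrial UMIs were kept, 10680 of 10685. Counts were log-normalised to 10000 per cell, and 2000 variable genes without Bach2, mitochondrial and ribosomal protein genes gave 30 principal components, 15 neighbours and Leiden clusters at resolution 0.8 (scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9, seed 1). Leading genes were ranked by fold against all other cells, with 10 CPM added, among genes with a UMI in at least 10% of the cluster's cells. A cluster was named when at least 3 markers of the class stood among its 30 leading genes and fewer than 2 markers of another class among the top 10. This naming rule was written after clusters had been seen and was once changed from fewer than 3 to fewer than 2, with no effect on the activated-like and resting-like classes. The change left unnamed a cluster of 89 cells that the looser rule names cycling-like. Clusters were drawn on 3 selections of cells, at 3 resolutions and from 5 seeds, and each is reported. No doublet caller was run. Leaving out cells with a UMI of Cd79a, Lyz2, Cd8a or Hbb-bs and the top 2% of cells by UMIs was an alternative.

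For the score, each of the 10555 Treg cells (all kept cells outside the B-cell-like and myeloid-like clusters) was thinned to 1000 UMIs, and 306 shallower cells were left out. The score was the mean log-normalised value of 28 activated markers minus that of 15 resting markers. Tertiles were taken within each set and held 3419, 3416 and 3414 cells. The lower tertile held 69.0% of scored resting-like cells and the upper 49.7% of scored activated-like cells. Unthinned UMIs were then summed, 8787651 in the lower and 7934002 in the upper tertile, and given as CPM with exact Poisson intervals. Ratios have intervals from the exact conditional binomial distribution (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15, matplotlib 3.10.9). Ratios of a single set had 0.5 UMIs added. Cells are not replicates, so no p-value was computed from them. Shares of cells have exact Clopper-Pearson intervals.

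Named genes were Bach2, Foxp3, the 12 largest folds each way among genes with over 20 CPM in 1 tertile and at least 200 UMIs over both (5103 genes), and the 4 members of each list with the largest ratio among those with at least 100 UMIs. The rule had been written for genotypes and was carried over to tertiles. The score's markers were left out of both. The lists were Treg identity, resting and lymphoid-homing T cell genes, activated and effector Treg genes, T helper lineage factors and cytokines, chemokine and homing receptors, AP-1 and BACH family factors, immediate early and dissociation stress genes, T cell receptor response, inhibitory receptors and suppressive molecules, NF-kB and TNF receptor family, cell cycle, interferon response, heme and NRF2 targets, apoptosis regulators, glycolysis, oxidative phosphorylation, quiescence-associated factors, markers of B, plasma, CD8, NK, myeloid, erythroid and follicular helper cells, sex-linked genes, ribosomal protein genes and mitochondrially encoded genes. Some genes stand in several lists. A list's median was ranked among 10000 random lists of the same size, matched on expression in 20 bins. Random genes were drawn independently of each other, so correlation between the genes of a list was not modelled.

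The steps were tested on simulated data for the comparison of tertiles. Of 5103 simulated genes, 200 were given a change, 100 by 2-fold and 100 by 1.5-fold. Each of the 2 sizes was recovered in the right direction for 100% of its genes, and the interval held the true value for 95.3% of genes. Coordinates and gene identifiers came from GENCODE M21 on mm10, in which 13621 of the 14098 symbols were found.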

Results

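Regulatory T (Treg) cells, the Foxp3-expressing T cells that restrain immune responses, were sorted by their EGFP reporter from the spleens of tamoxifen-treated C57BL/6 mice aged 18 to 21 weeks, and their RNA was profiled by droplet-based 3′ single-cell sequencing. The 6 samples comprised 3 from mice with loxP-flanked Bach2 and a tamoxifen-inducible Cre recombinase expressed from the Foxp3 locus (conditional knockout, cKO) and 3 from mice with wild-type Bach2 and the same Cre (WT). Bach2 is a transcriptional repressor of lymphocytes that competes with AP-1 factors for DNA. The count table held 25389602 unique molecular identifiers (UMIs), and levels are given in CPM, counts of a gene's UMIs relative to all UMIs, scaled to 1000000. The cells fell into 6 sets by barcode suffix, with 1641 to 1902 cells, 3998172 to 4786590 UMIs and a median of 2003 to 2229.5 UMIs per cell in each. No name in the table tied a set to a sample, so the cKO and WT samples were not compared, and values are given over all sets or as a range over the 6 sets. There were therefore no replicates of a group, and every interval below is a 95% interval that covers counting error only.

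Bach2, the targeted gene (chromosome 4, 32238804 to 32586108, plus strand, mm10; ENSMUSG00000040270.16, protein coding), was detected in each set. Its level in Treg cells ranged from 19.0 to 36.9 CPM over the 6 sets, with a median of 28.0. The part of the gene flanked by loxP sites was not given in the sources used here, and a 3′ tag outside the deleted part is counted with or without the deletion, so these levels did not check the genotype labels. Foxp3 (chromosome X, 7573644 to 7595245, plus strand, mm10; ENSMUSG00000039521.13, protein coding), the factor that defines Treg cells, lay between 19.7 and 22.6 CPM. With each cell thinned to 1000 UMIs, 2.16% of Treg cells had a Foxp3 UMI (exact binomial interval 1.88 to 2.46%). Among B-cell-like and myeloid-like cells 0 of 116 had one, which allows a share of up to 2.59% by 3 counts of the total and 3.13% by the exact interval, so the share of cells did not separate Foxp3 in Treg cells from free RNA at this depth. The unthinned shares were 4.85% and 2.40%, at median depths of 2092 and 2021 UMIs. Ikzf2, which encodes the Treg factor Helios, had a UMI in 59.8% of thinned Treg cells (58.8 to 60.7%) and in 21.6% of the B-cell-like and myeloid-like cells (14.5 to 30.1%).

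Most sorted cells carried the markers of activated or resting Treg cells, and few those of other cell types. Of the 10680 cells kept, 6152 (57.6%) lay in 3 activated-Treg-like clusters. The leading genes of 1 of these (1680 cells) were S100a4, Ccr2 and S100a6, those of another (1883 cells) Il1r2, Bcl2a1d, Penk, Tnfrsf9 and Cd83, and those of the last (2589 cells) Ccl5, Asb2, Lilrb4a and Maf. The resting-Treg-like cluster, with Igfbp4, Ly6c1, Satb1 and Ccr7 among its leading genes, held 2762 cells (25.9%). An interferon-response-like cluster led by Ifit3, Ifit1 and Isg15 held 285 cells, a B-cell-like cluster 92 and a myeloid-like cluster 33. The remaining 1356 cells stayed unnamed. They comprised 1212 cells led by Dnah7a, Lta and Lrrc32, 55 cells led by Tmem176b and Tmem176a, and 89 cells led by the globin genes Hba-a1 and Hbb-bs that also had 13 cycling markers among their 30 leading genes and a median of 7870 UMIs. When 4 cells with over 50% erythroid UMIs were left out before clustering, a cluster of 76 cells with 13 cycling markers was named cycling-like. The activated-like share ranged from 46.1 to 66.9% and the resting-like share from 17.7 to 34.96% over the sets. The activated-like share was not a firm value, since other clusterings of the same data gave 35.6 to 62.5%. The Ccl5 cluster had only 4 activated markers among its 30 leading genes. In some of the other clusterings a large cluster that shared leading genes with it stayed unnamed.

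Bach2 RNA was lower in activated-like than in resting-like Treg cells. It stood at 19.6 CPM in the activated-like clusters (17.3 to 22.1, from 261 UMIs) and at 45.6 in the resting-like cluster (40.8 to 50.8, from 329 UMIs). The log2 ratio was -1.22 (-1.46 to -0.98), and Bach2 was lower in the activated-like cells of 6 of 6 sets, with log2 ratios from -1.84 to -0.70. This ratio pooled sets with different Bach2 levels and class shares, and in 5 of the 6 sets the set's own ratio lay further from 0 (median of the sets -1.49). Bach2 was at 14.2 CPM in the S100a4 cluster, 16.4 in the Ccl5 cluster and 26.5 in the Il1r2 cluster, also pooled over sets, so these 3 clusters are not ranked. Foxp3 was at 20.6 CPM in activated-like and 20.5 in resting-like cells. Bach2 itself was kept out of the genes used for clustering. The comparison had been planned for the WT samples alone, as a fit with library as block. Here it covers both genotypes together and the pooled ratio has no such block.

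A score per cell gave the same direction without cluster borders. It used the markers that also named the 2 classes, on the same cells, so it is not independent support. The score was the mean of 28 activated-Treg markers minus the mean of 15 resting-Treg markers, and the 10249 scored Treg cells were divided within each set into a lower, a middle and an upper tertile. Bach2 stood at 39.6 CPM in the lower tertile (35.5 to 44.0), 25.3 in the middle (21.9 to 29.0) and 18.0 in the upper (15.2 to 21.2). The log2 ratio of the upper over the lower tertile was -1.14 (-1.43 to -0.85), and Bach2 was lower in the upper tertile of 6 of 6 sets, from -2.06 to -0.16. Each tertile is a range of the score rather than a cell type, and 2180 cells (21.3%) lay within 0.05 of a boundary. Foxp3 was at 22.1, 22.2 and 19.8 CPM in the lower, middle and upper tertile, a log2 ratio of -0.16 whose interval (-0.47 to 0.15) included 0. The Bach2 ratio depended on the random thinning: 20 other draws gave -1.17 to -0.87 with a median of -1.06, Bach2 was lower in 6 of 6 sets in each draw, and thinning to 500 UMIs gave -0.72. Cells of the upper tertile were shallower, with a median of 1938.5 UMIs against 2421 in the lower.

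**Figure D1:**
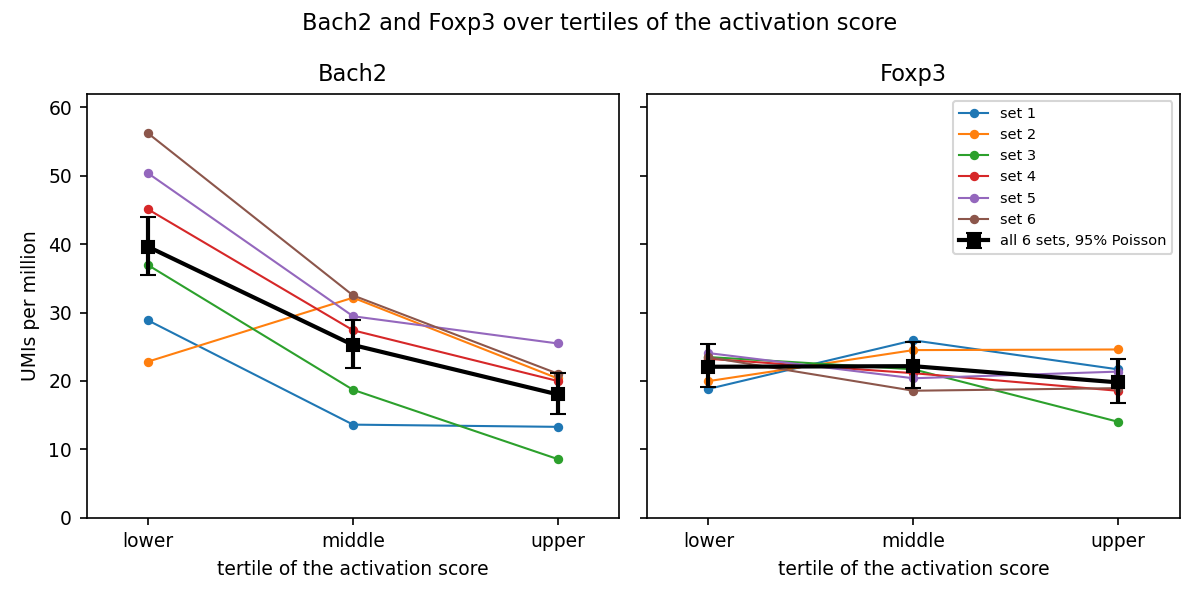
CPM of Bach2 (left) and Foxp3 (right) in the lower, middle and upper tertile of the activation score. Thin lines are the 6 barcode sets and the black line is all sets together with exact 95% Poisson intervals. Bach2 went from 39.6 to 18.0 CPM and Foxp3 from 22.1 to 19.8.

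Among genes outside the score with over 20 CPM in 1 tertile and at least 200 UMIs over both, Cxcr6, Lgals3, Il1r2 and Ccr2 had the highest ratios of the upper over the lower tertile. Some genes with fewer UMIs had ratios as high, such as Areg (log2 ratio 3.09). The chemokine receptor gene Cxcr6 was 9.14-fold higher (45.8 against 5.01 CPM, log2 ratio 3.19, 2.74 to 3.68). Lgals3, which encodes galectin-3, was 7.26-fold higher, Il1r2, a decoy receptor for interleukin-1, 6.91-fold, the chemokine receptor gene Ccr2 6.58-fold and Lilrb4a, an inhibitory immunoglobulin-like receptor gene, 5.78-fold. Next under these limits came Ccnb2, which encodes cyclin B2 (5.34-fold), Bcl2a1d, an anti-apoptotic Bcl-2 relative (4.81-fold), Rgs16 (4.69-fold), Asb2 (4.58-fold), the adhesion gene Alcam (4.55-fold), Gna15 (4.46-fold) and Ube2c, a ubiquitin-conjugating enzyme gene of mitosis (4.45-fold). These 12 genes, picked for their ratio over the same sets together, were higher in the upper tertile of 6 of 6 sets. Without the 89 cells that held the cycling markers, Ccnb2 gave a log2 ratio of 0.41 in place of 2.42 and Ube2c 0.98 in place of 2.15. Over 24 alternatives to the comparison, the lowest ratio was 0.41 for Ccnb2 and 0.24 for Ube2c. Bcl2a1d has a near-identical paralog, Bcl2a1b, and the separate values of the 2 genes are uncertain.

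Of the 12 genes with the lowest ratios under the same limits on CPM and UMIs, 8 were lower in the upper tertile of 6 of 6 sets. Gata1, a transcription factor gene known from the erythroid lineage, was at 4.66 against 26.1 CPM (log2 ratio -2.48, -3.02 to -1.98). The others were Treml2 (-1.77), the Tec-family kinase gene Txk (-1.30), Bach2 (-1.14), Gm4951 (-1.13), the Ras-related gene Rras2 (-1.06), Sh3bp5 (-1.01) and Rab3ip (-0.99). The remaining 4 were globin genes, Hba-a2 at -4.36, Hbb-bt at -4.04, Hba-a1 at -3.77 and Hbb-bs at -3.19, lower in only 3 or 4 of the 6 sets. In 4 cells, erythroid genes made up 71.3 to 86.7% of UMIs, against at most 0.340% in any other cell, and these 4 cells held 90.8% of the Hbb-bs UMIs. Without them the 4 globin ratios lay between -0.34 and -0.03, and without barcode set 5, which held 2 of them, Hba-a2 was at 0.05, Hba-a1 at 0.14, Hbb-bs at -0.23 and Hbb-bt at -1.14. Gata1 gave -2.24 without the 4 cells.

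**Figure D2:**
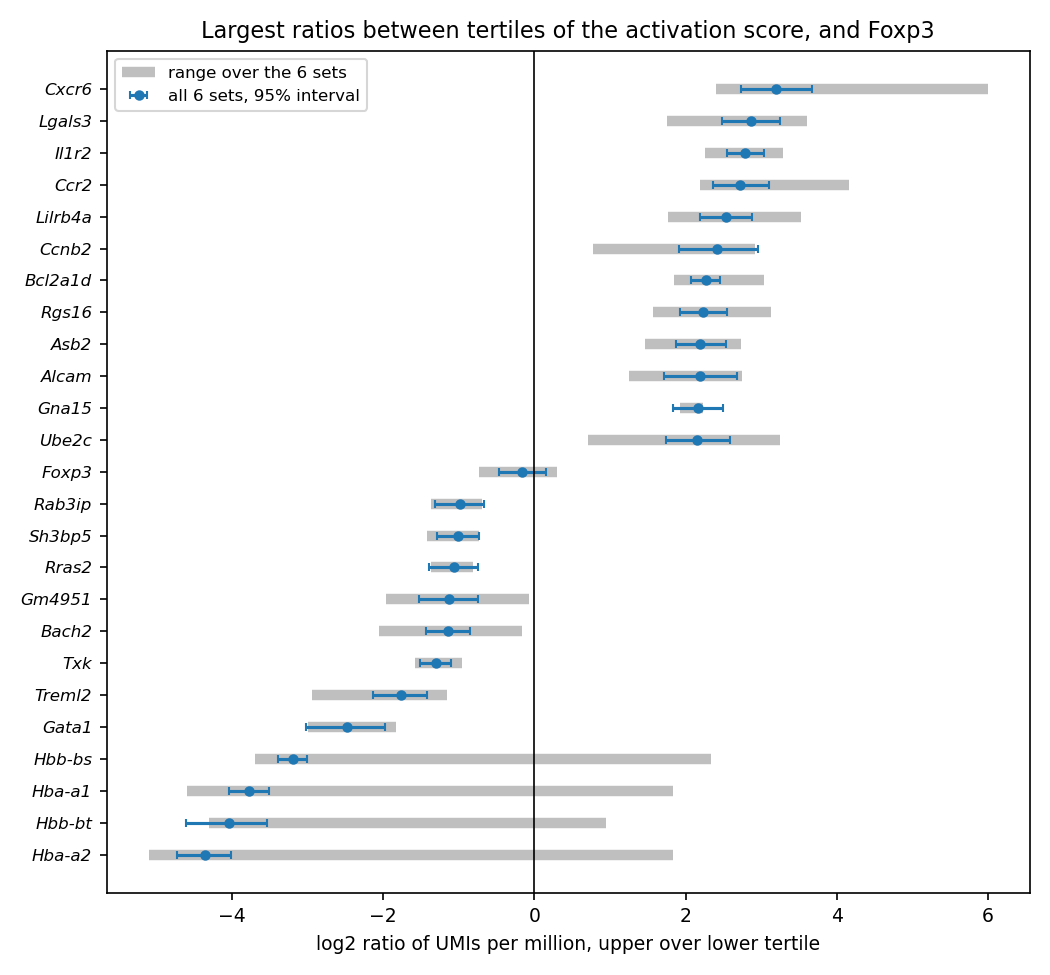
Log2 ratio of CPM, upper over lower tertile, for Foxp3 and the 12 genes with the largest ratio in each direction among those with over 20 CPM in 1 tertile and at least 200 UMIs. Blue points are all sets together with 95% counting intervals, and grey bars span the 6 sets. The grey bars of the 4 globin genes cross 0, while those of Cxcr6 (2.41 to 6.00, the latter from 0 UMIs in a lower tertile) and Gata1 (-3.00 to -1.83) do not.

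For the gene lists, a member was called higher or lower when its ratio was at least 1.5-fold and in the same direction in 6 of 6 sets. The direction alone, without the limit on size, is shared by chance by 3.13% of genes without a change. The share of all measured genes that met the full rule is not given here. The counts of called members therefore do not show an excess over other genes. The median of the 8138 genes measured was itself 0.18 higher in the upper tertile (log2), so counts and ratios in the next paragraphs are relative to that median gene, with counts from plain CPM beside them where they differ. Of 9 measured genes of activated and effector Treg cells outside the score, 9 were higher, among them Areg (2.91), which encodes the growth factor amphiregulin, Id2 (1.86), the inhibitory receptor gene Lag3 (1.69) and Il1rl1 (1.56), the interleukin-33 receptor gene. This list's median ranked above each of 10000 random lists of matched expression, but its genes were chosen for the state that the score measures. Of 16 T cell receptor response genes, 6 were higher and 0 lower (8 and 0 in plain values), with Egr2 at 1.58, Nfkbid at 1.22, Nr4a3 at 0.85 and Tox at 0.85. The NF-kB and TNF receptor family had 6 of 20 higher and 0 lower (8 and 0), with Bcl2a1d at 2.08, Bcl2a1b at 1.73, Nfkb2 at 1.02 and Nfkbia at 0.79. Both medians lay above each random list, but each of these lists also held 3 markers of the score, left out here. They thus overlap the state that the score measures. Bcl2a1d and Bcl2a1b, whose separate values are uncertain, both count among the 6 NF-kB calls.

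Called genes of Treg identity went both ways, while the list's median ranked at percentile 99.95 of the random lists. Of 19 measured, 5 were higher and 4 lower (9 and 3 in plain values). Higher were Itgb8 (1.32), an integrin gene that activates TGF-beta, Ikzf2 (0.80), Nrp1 (0.73), Tnfrsf18 (0.72), which encodes GITR, and Swap70 (0.64). Lower were Gpr83 (-0.90), Lrrc32 (-0.83), which encodes the TGF-beta docking protein GARP, the interleukin-2 receptor gene Il2ra (-0.79) and Socs2 (-0.59). Without cells carrying UMIs of other cell types and the deepest 2% of cells, the plain counts were 7 higher and 0 lower. Of 13 inhibitory receptors and suppressive molecules, 4 were higher and 1 lower (8 and 1 in plain values). Lag3, Itgb8 and Ebi3 (1.22), a subunit gene of interleukin-35, were among the higher, Cd160 was at 0.92 and the lower member was Lrrc32. Without the same cells, the plain counts were 7 higher and 0 lower. The chemokine and homing receptors had 3 of 10 higher (4 in plain values), Cxcr6 at 3.01, Ccr2 at 2.54 and Ccr4 at 0.98, and Ccr6 at 0.45 was not called. The T helper lineage factors and cytokines had 4 of 12 higher, Il1rl1, Gata3 (0.93), Il12rb1 (0.83) and Il18r1 (0.67), and Tbx21, at 0.72, was higher in only 4 sets. Swap70, Gpr83, Lrrc32, Il2ra, Socs2 and Il18r1 were named after their values were seen. Among the random lists, the medians were at percentile 100 for inhibitory receptors, 99.55 for chemokine receptors and 93.98 for T helper genes. These lists also held 6, 7 and 1 markers of the score, left out here.

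Resting genes outside the score were lower in the upper tertile for 4 of 8 members, Txk (-1.49), Nsg2 (-1.16), Foxp1 (-0.96) and Il6st (-0.74), and higher for 0 (plain values: 3 lower). Of 18 quiescence-associated factors, 2 were lower, Foxp1 and the glucocorticoid-induced gene Tsc22d3 (-0.94), and 0 higher, with Cdkn2d at -0.58 and the cell cycle inhibitor gene Cdkn1b at 0.23. Of 24 interferon response genes, 3 were lower, Slfn5 (-1.06), Usp18 (-1.02) and Oasl2 (-0.99), and 0 higher, with the abundant Ifi27l2a at 0.33. The interferon count was 0 when cells carrying UMIs of other cell types and the deepest 2% of cells were left out. The median of the interferon list lay below each random list, and that of the quiescence list at percentile 0.12. The median of the resting list also lay below each random list, but its genes were chosen for the state that the score subtracts. In the AP-1 and BACH family, Bach2 (-1.32) was lower and Junb (0.63) higher among 11 members (2 higher in plain values), while Mafg was at 0.52 and Jund at 0.29. This list's median was at percentile 68.3 of the random lists.

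Cell cycle genes had 10 of 24 members higher (12 in plain values), led by Ccna2 (2.42), Ccnb2 (2.23), Ube2c (1.97) and Birc5 (1.78). Without the 89 cells of the cluster holding the cycling markers 0 members passed in plain values, and 2 passed without cells carrying UMIs of other cell types and the deepest 2% of cells. Ccna2 stood at -0.67 (plain log2 ratio) without the 89 cells. Apoptosis regulators had 4 of 17 higher (6 in plain values, and 3 without cells carrying UMIs of other cell types and the deepest 2% of cells), with Bcl2a1d, Bcl2a1b, the pro-apoptotic gene Pmaip1 (1.55) and the anti-apoptotic gene Bcl2l1 (0.99), and 1 lower, the pro-apoptotic gene Bcl2l11 (-1.01), named after its value was seen. Immediate early and dissociation stress genes had 4 of 22 higher (5 in plain values), Gadd45b (1.41), Hspa1a (0.70), Dusp1 (0.67) and Junb, and 1 lower, Socs3 (-1.08). Glycolysis genes had 1 of 14 higher, Tpi1 (0.60), against 3 in plain values, and Pfkl was at 0.49, Pgam1 at 0.42 and Gapdh at 0.32. Heme and NRF2 target genes had 1 of 14 lower, Blvrb (-0.98), and 0 higher (0 and 0 without cells carrying UMIs of other cell types and the deepest 2% of cells), with Prdx1 at 0.25, Txn1 at 0.22 and Osgin1 at 0.21. None of 24 oxidative phosphorylation genes was called, and Cox8a was at 0.25, Ndufa4 at 0.13, Ndufb8 at 0.11 and Cox5a at 0.11. Among the random lists, the medians were at percentile 100 for cell cycle, 99.98 for glycolysis, 99.93 for apoptosis and 98.92 for immediate early genes. Those of the heme and oxidative phosphorylation lists were at percentiles 79.11 and 75.93. Of 89 ribosomal protein genes, 7 were lower, among them Rpl35 (-0.64), Rps7 (-0.64) and Rpl12 (-0.63), against 0 in plain values. The list as a whole was lower, with a median of -0.47 (-0.29 in plain values) that lay below each random list. With totals without ribosomal and mitochondrial genes, ratios shifted by 0.168, most of the 0.183 of the median gene. This list was defined by symbol and also held the kinase gene Rps6kb2 (0.36). Of 13 mitochondrially encoded genes 0 were called, with mt-Nd6 at -0.54, mt-Nd3 at 0.01, mt-Co2 at -0.08 and mt-Nd1 at -0.09, the last 2 being above 0 in plain values.

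**Figure D3:**
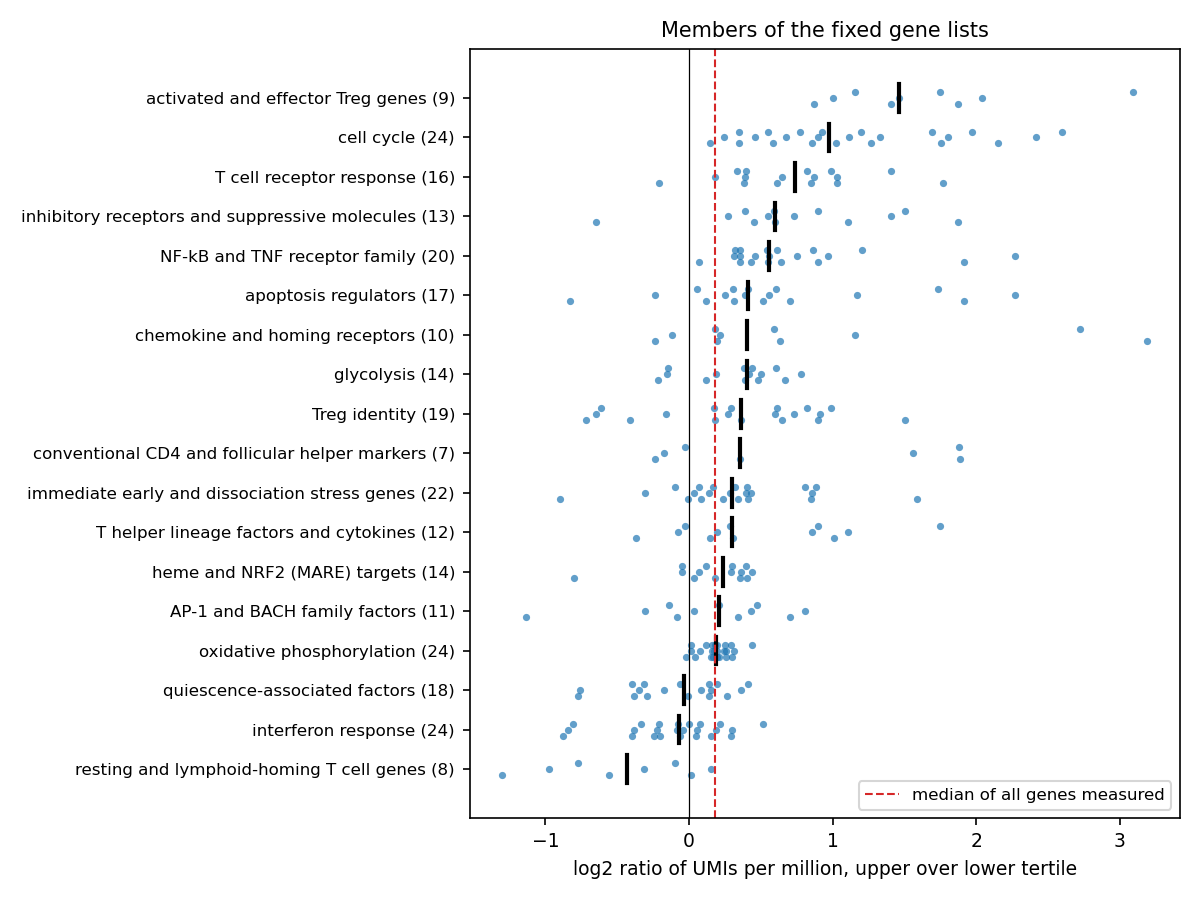
Log2 ratio of CPM, upper over lower tertile, for each measured member of 18 fixed gene lists with at least 7 measured (number in brackets), ribosomal and mitochondrially encoded genes not shown. Points are genes, black bars are list medians and the dashed red line is the median of all genes measured (0.18). Among the lists shown, the medians ran from -0.43 for the resting list to 1.46 for the activated list.

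No marker of other cell types was called lower in the upper tertile, and the ratios of members not called lay on both sides of 0. Of 5 B cell markers measured, 1 was higher, Cd74 (1.14), the invariant chain gene, against 2 in plain values, and Cd79b was at 0.44, H2-Eb1 at 0.31 and H2-Aa at 0.28. Of 5 myeloid markers 0 were called, with Plac8 at -2.14 in 5 of 6 sets, Cst3 at 0.34, S100a9 at -0.47 and S100a8 at -0.01. The 1 measured NK and cytotoxic marker, Nkg7, was higher (1.27), and the 1 measured CD8 marker, Cd8b1, was at -0.08. Plasma cell markers had 0 of 2 called, with Jchain at 0.20 and Xbp1 at 0.07, and erythroid and platelet markers 0 of 5. Of 7 conventional CD4 and follicular helper markers, 2 were higher, Angptl2 (1.71) and Tox2 (1.37), while Sostdc1 (1.70) was higher in 5 of 6 sets and Cd40lg was at 0.17. The size for Sostdc1 was not firm: its plain log2 ratio was 1.88, 3.46 without thinning, 3.49 with cells thinned to 500 UMIs and 1.25 without barcode set 1. The sex-linked genes Xist (0.32) and Tsix (0.10) were not called.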

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

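All tests of explanations in this part were chosen after the results had been seen. The spread over barcode sets was examined for 62 values with Dixon's criterion, although the 6 sets are of unassigned genotype and are not a replicate group. The criterion was passed by 3 values, and chance alone passes it for about 1 in 20.

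The log2 ratio of Cxcr6 between the upper and the lower tertile was 6.00 in set 3, above the other sets, of which the lowest was 2.41. Set 3 had 27 Cxcr6 UMIs in the upper and 0 in the lower tertile, so the added 0.5 UMIs set the size of this ratio and it is not a measured outlier. The ratio of Hba-a2 was -5.10 in set 5 (40 UMIs in the upper and 1561 in the lower tertile), far below the other sets, which had at most 24 UMIs in a tertile, and set 5 held 2 of the 4 cells made up mainly of erythroid UMIs.

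The ratio of Ccnb2 was 0.78 in set 1 (19 and 13 UMIs), well below the other sets, of which the highest was 2.91. The higher level of cell cycle genes in the upper tertile may come from the few cells of the cluster that held the cycling markers. Without its 89 cells, the median log2 ratio of the list exceeded that of all genes by 0.15 (0.33 against 0.18), between the bounds set for and against this explanation, and 0 of 24 members passed the size rule. Whether the whole excess came from these cells therefore cannot be told apart from a smaller shift in the other cells. These cells had a median of 7870 UMIs and no doublet caller was run, so doublets stay open, and no biological explanation was tested.

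Part of the cells that the authors' normalized table leaves out held RNA of other cell types. Cd79a, a B cell receptor gene, was at 501.7 CPM there against 5.10 in the cells of that table, and Lyz2, a myeloid gene, was at 1411.4 against 11.7. Of the 123 left-out cells within the limits on genes and mitochondrial share, 91 lay in the B-cell-like and 27 in the myeloid-like cluster. Cd79a was at 1742 CPM in these 123 cells and at 23.6 in the 98 past a limit, and Lyz2 at 4029 and 403. Of those 98 cells, 42 lay in activated-like clusters, 41 in unnamed clusters, 1 in the B-cell-like and 4 in the myeloid-like cluster.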

How the results depend on the processing

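The alternatives to the tertile comparison, the other seeds, the looser naming rule, the exclusion of erythroid cells and resolution 1.2 for the Bach2 ratio between classes were chosen after seeing the data. The planned tests between genotypes were not run, because no column was tied to a sample: edgeR and DESeq2 fits and their normalizations, filters and left-out libraries, gene list tests, fits within classes, the interaction, equal cell numbers, clustering without called genes and the normalized table by genotype. No paired analysis was possible because the columns carry no replicate number.

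The ratio of Bach2 between activated-like and resting-like cells kept its direction under each of 8 alternatives, from -1.25 to -1.01, and with 1 set left out at a time from -1.33 to -1.17. Between tertiles it stayed below 0 under each of 24 alternatives, from -1.32 (centred on the median gene) to -0.72. It left the main interval with cells thinned to 500 UMIs (-0.72) and without marker-positive cells and the top 2% by UMIs (-0.79), and the cause was not tested. With 1 set left out it ran from -1.28 to -1.02. The median score of the sets was 0.057, 0.058 unthinned and 0.062 at 500 UMIs, and 0.011 to 0.103 with 1 set left out.

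The share of activated-like cells depended on the clustering. From 57.6% it went to 50.6% at resolution 0.4, 43.5% at 1.2, 35.6% with all deposited cells, 39.9% without the erythroid cells and 62.5%, 37.0%, 43.4% and 37.9% with seeds 2, 3, 4 and 5. It stayed at 57.6% with the looser naming rule and ran from 55.7 to 60.0% with 1 set left out. The Ccl5 cluster (2589 cells) had Impact and St6galnac3 among its leading genes and the lowest median depth, 1693 UMIs. With all deposited cells, without the erythroid cells and with seed 5, clusters of 3507, 2868 and 2867 cells shared these 2 genes. They had 0 markers among their 30 leading genes and stayed unnamed. Whether they held the same cells, and the cause of the shifts, was not tested.

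For 106 named genes under 24 alternatives, 2127 of 2543 ratios stayed in the main interval and 392 left it without counting as reversed. A reversal was counted only where the main interval excluded 0. The 392 therefore also hold changes of sign, such as Foxp3 at 0.20 in another thinning draw against -0.16. The other 24 ratios reversed, in 11 genes. With all deposited cells the ratios were 4.34 for Hba-a2, 3.71 for Hbb-bt, 3.81 for Hba-a1, 3.21 for Hbb-bs, -0.031 for Cd79b, -0.62 for H2-Eb1 and 0.32 for Plac8. With tertiles over all sets together they were 0.23 for Hba-a2, 0.017 for Hbb-bt, 0.29 for Hba-a1 and 0.17 for Hbb-bs. Hba-a1 was at 0.14 without thinning. Without marker-positive cells and the top 2% by UMIs, Hba-a2 was at 0.32 and Hba-a1 at 0.18. With 1 set left out Hba-a2 ran from -4.85 to 0.050 and Hba-a1 from -4.30 to 0.143, and both highest values came without set 5. Among cells of 1800 to 2400 UMIs, Hba-a2 was at 0.015, Hba-a1 at 0.51 and Ccr6 at -0.059. With totals without ribosomal and mitochondrial genes, mt-Co2 was at -0.061 and mt-Nd1 at -0.075, and centred on the median gene at -0.076 and -0.090. Ccna2 was at -0.67 without the cluster holding the cycling markers. For the globin genes 4 cells held most UMIs; for the others the cause was not tested. Depth limits single genes: Bach2 ratios rest on 143 UMIs in the upper and 348 in the lower tertile, and other thinning draws shared 71.3 to 73.3% of the upper tertile's cells, so the order of named genes is not firm.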

Other observations

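The tests of the Bach2 pattern and the genes compared in the Tmem176 cluster were chosen after the results had been seen. The test of Cxcr5 was written before its result, and the other genes set beside it, the comparison within the upper tertile and the clustering of sets without globin genes were chosen afterwards.

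A cluster of 55 cells was led by Tmem176b, Tmem176a, Prg4, Serpinb1a and Ccr2. Against the other 10500 Treg cells it had more Ccr6 (41.9 against 9.39 CPM, from 5 and 234 UMIs, log2 ratio 2.16, 0.52 to 3.40) and Maf (285 against 130, 1.13, 0.60 to 1.62) and less Ikzf2 (394 against 1024, -1.38, -1.82 to -0.97). The cluster was drawn from the same counts, and these intervals do not cover that selection. The intervals for Gata3 (0.22), Il1rl1 (0.01), Foxp3 (0.66) and Bach2 (0.26) included 0.

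At least 1 UMI of Sostdc1 or Angptl2, known from follicular T cells, was counted in 277 of 10555 Treg cells (2.62%, 2.33 to 2.95%) and in 0 of 125 B-cell-like and myeloid-like cells, for which the exact upper limit was 2.91%. Free RNA as the source of these UMIs was therefore not excluded. Against the other 10278 Treg cells, the 277 had more Tox2 (1.73, 1.23 to 2.19) and Pdcd1 (1.34, 1.10 to 1.57) and less Ccr7 (-0.30, -0.61 to -0.00048). Ikzf2 was at 0.17 (0.07 to 0.27). The intervals for Bcl6 (0.42), Foxp3 (-0.32), Bach2 (0.13) and Sh2d1a (-0.03) included 0. As a hypothesis, they may be follicular regulatory T cells. Cxcr5, the receptor of follicular cells, gave a log2 ratio of 0.68 (-0.14 to 1.41), which neither reached the 2-fold rise set beforehand nor excluded it, and 16 UMIs against 296 keep this open. Over all sets together both genes were higher in the upper tertile, but only Angptl2 was called higher. For Sostdc1 the lowest log2 ratio of a set was -0.38, and the pooled size depended on the thinning (1.88, and 3.46 unthinned). The contrast of the 277 cells with the other Treg cells was thus not matched for activation. Within the upper tertile (146 against 3268 cells), Tox2 (1.57, 0.93 to 2.16) and Pdcd1 (0.90, 0.60 to 1.19) were still higher, while the intervals for Cxcr5 (0.72, -0.64 to 1.83), Ccr7 (-0.012) and Ikzf2 (0.050) included 0. Differences in the score within that tertile were not matched, and Pdcd1 and Ccr7 are themselves markers of the score.

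The lower Bach2 in the upper tertile was set against 3 technical explanations. A depth difference between tertiles as the whole cause was argued against by cells of 1800 to 2400 UMIs, in which the ratio was -0.86 (-1.54 to -0.21). RNA of B cells in the lower tertile, judged from Cd79a (5.01 against 6.18 CPM in the lower and upper tertile), could bring 0.156 CPM of Bach2, against a difference of 21.6. Conventional T cells in the lower tertile as the whole cause were argued against by cells with UMIs of at least 2 of Foxp3, Il2ra and Ikzf2, in which the ratio was -1.04 (-1.68 to -0.44, from 81 and 32 UMIs), although free RNA of these genes lets some other cells pass. A lower Bach2 in more activated Treg cells is thus a hypothesis found and tested on the same cells, and its dependence on genotype was not tested.

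The barcode sets, whose genotype was not assigned, had these values in Treg cells in the order of suffixes 1 to 6. Bach2 was at 19.0, 24.9, 22.5, 31.2, 35.6 and 36.9 CPM. Igfbp4 was at 118, 101, 109, 36.8, 35.1 and 33.7. S100a6 was at 194, 220, 167, 412, 413 and 350, and Cxcr3 at 74.1, 69.5, 68.3, 120, 132 and 116. Prdm1, which encodes Blimp-1, was at 7.24, 7.61, 6.47, 14.5, 14.4 and 14.5. Foxp3 was at 21.9, 22.6, 19.7, 20.8, 22.2 and 20.2. The activated-like share was 52.1, 50.1, 46.1, 66.9, 66.7 and 65.1%, and the resting-like share 28.3, 34.0, 34.96, 18.2, 20.8 and 17.7%. The median score was 0.011, -0.0016, -0.0040, 0.156, 0.143 and 0.103. Over 7510 genes, hierarchical clustering placed sets 1, 2 and 3 on 1 branch and sets 4, 5 and 6 on the other, and correlations across genes between pairs of sets were 0.976 to 0.989. The correlations did not follow these branches throughout: set 1 was at 0.98558 with set 5 and 0.98473 with set 6, against 0.98315 with set 2 and 0.98427 with set 3, and set 4 was at 0.98545 with set 2 against 0.98254 with set 5. Without the 4 globin genes the branches held the same sets, and correlations were 0.98748 to 0.98963 within a branch and 0.98279 to 0.98670 between branches. Genes are not independent replicates. Over all deposited cells Hbb-bs was at 617, 1.25, 2.37, 2.39, 1615 and 107 CPM, in line with the sets of the 4 erythroid cells, without which its ratio between tertiles was -0.19.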
